A study of Mus musculus with 6 samples.

How the data were processed

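Messenger RNA was sequenced from basal epithelial cells of the mouse mammary gland, the outer layer of the gland that holds the contractile myoepithelial cells. Per the labels, the glands were digested with collagenase and basal cells were sorted by flow cytometry as live cells negative for CD45 (leukocytes) and CD31 (endothelium), low for CD24 and high for CD49f. The mice were 15 weeks old and of a mixed 129/Sv and C57BL/6 background, and each sample pooled cells of 2 to 3 mice. There were 2 wild-type libraries and 4 libraries from mice homozygous for the Vim knockout allele.

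The deposited files hold raw read counts per gene, which the authors made with featureCounts 1.5.1 per the file headers. Per the same headers, reads were counted over exons of the UCSC mm10 gene annotation in the reverse-stranded setting (option 2), without the options for multi-mapped reads and for reads that overlap several genes. Reads shared between near-identical genes or overlapping exons were therefore left out of the counts, and the values of such genes are uncertain. Base calls, alignment and counting used bcl2fastq 2.17, STAR 2.5.2b and Subread 1.5.1, per the submitters' processing notes. Libraries were prepared with a stranded mRNA kit, per the labels' protocols. The files list 23337 genes with their coordinates on mm10, and every value was a whole number.

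Total counts per library ran from 25347967 to 31200622. At this depth counting error is small for all but the lowest genes. Intervals and lower bounds given for such genes cover counting error only, since the reads carry no molecular identifiers.

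Expression was compared with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 13925 genes and set 9412 aside, and libraries were scaled by TMM. Genotype was the only term of the model (glmQLFit, robust, and glmQLFTest, 2-sided), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 fold changes are knockout minus wild type, and values per library are CPM, computed here on the TMM scale. Log2 CPM used a prior count of 2. Gene lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01, over lists with at least 5 tested members, and again with a correlation estimated from the data and with fry. The lists, the tests, the rule for the genes named and most alternatives were fixed before the data were examined. Of 33 lists, 31 were tested. The erythroid list and the list of mitochondrially encoded genes had too few tested members and gave no result.

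The genes named were Vim, Snai2, Krt5, Krt14, Trp63, Acta2, Itga6, Cd24a, Krt8, Krt18, Ptprc and Pecam1 in every case; up to 10 called genes per direction with a mean log2 CPM of at least 1 and all knockout libraries on the same side of both wild-type libraries; the leading members of each list by p, up to 4 for called lists and 2 for others; and called genes within 10 Mb of Vim. Predicted genes were left out of the rule. The same rule was applied, after the data were seen, to the fit with the replicate block, with each knockout library set against the wild-type library of its own experiment. Other genes named are said to have been chosen after their values were seen.

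The labels speak of 2 independent experiments without assigning samples. A day code in the names of the deposited files divides the libraries into experiment 1 (wild type 1, knockout 1 and 2) and experiment 2 (wild type 2, knockout 3 and 4). It was used as a technical batch only. Deviations from the group means correlated between wild-type and knockout libraries of the same experiment (r = 0.32, 0.29, 0.25 and 0.41 across genes) and negatively across experiments (r from -0.41 to -0.25). With 2 wild-type libraries the deviations mirror each other, so these values are not independent. The experiment was taken to pair the libraries, and a fit with it as a replicate block called 217 genes, which is given beside the results it changes.

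The numbers in the sample titles did not pair the libraries. Each library was also left out in turn, and size factors, low-count filters, the test and the thresholds were varied. DESeq2 1.42.0 and limma-voom were the other tests. On simulated counts for 13671 tested genes with 200 genes changed, the comparison of knockout with wild type recovered 44% of 2-fold and 76% of 4-fold changes by genotype alone, with 0% false calls. The simulated fit with the replicate block recovered 76% and 91%, with 10.2% of its calls false, above the nominal share. The test of the experiments, simulated over 13623 genes, recovered 79% of 2-fold and 92% of 4-fold changes with 10.9% false calls, and the interaction test over 13626 genes recovered 27% and 72% with 13.2% false calls. Each of these simulations was drawn once, so the spread of its shares is not known. With no list changed, a single simulated data set gave 0 called lists. Genes were drawn independently there, so this does not gauge how correlated list members affect the camera calls. A search over Reactome pathways, from the mouse set in fgsea 1.28.0, was added after the data were seen. Figures were drawn with matplotlib.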

Results

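The libraries came from sorted basal cells of 2 wild-type and 4 Vim knockout samples, each a pool of 2 to 3 mice. Vim encodes vimentin, an intermediate filament protein of mesenchymal cells that basal mammary cells also contain. Total counts were 31200622 and 27342539 in wild type 1 and 2 and 30771258, 25347967, 30159052 and 25963166 in knockout 1 to 4. Pearson correlations of log2 CPM between libraries ranged from 0.970 to 0.989 across genes. Over the 500 genes used for principal components, the leading component held 38.8% of the variance and separated the genotypes, and the next held 29.3% and separated the 2 experiments.

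**Figure D1:**
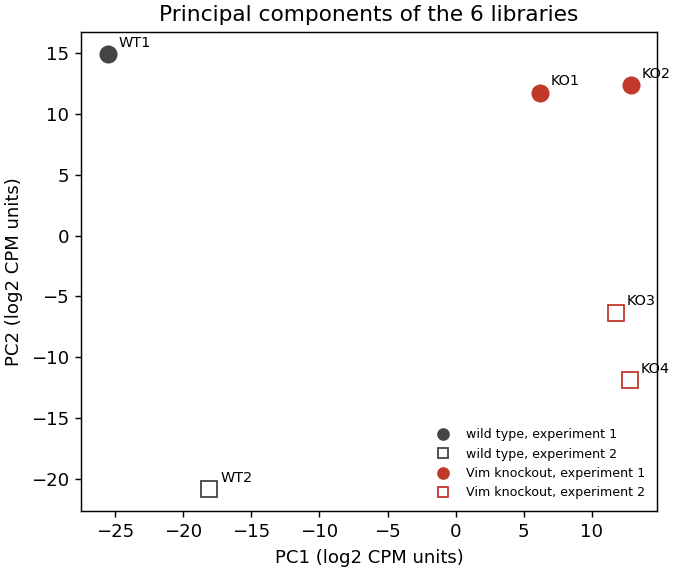
Scores of the 6 libraries on principal components 1 and 2 in log2 CPM units, with wild type in grey, knockout in red, filled circles for experiment 1 and open squares for experiment 2. The wild-type libraries lie at -25.6 and -18.1 on the horizontal axis and the knockout libraries between 6.21 and 12.9.

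Vim itself, at chromosome 2, positions 13574311 to 13582826 (mm10), fell to 46.1% of its wild-type level. Its counts were 7055 and 6256 in wild type 1 and 2 and 2938, 2645, 3318 and 2827 in knockout 1 to 4. The level was 228 ± 18.5 CPM (SD, n = 2) in wild type and 105 ± 8.96 CPM (SD, n = 4) in knockout, a log2 fold change of -1.12 (SE 0.12, edgeR adjusted p = 0.019), lower in 4 of 4 knockout libraries. Within the experiments the log2 differences were -1.13 and -1.11. With the replicate block the adjusted p was 7.14e-04. The counts do not tell exons apart, so the part of the gene that the remaining reads cover was not analysed here. Without wild type 1, wild type 2, knockout 2, knockout 3 or knockout 4 the log2 fold change stayed between -1.18 and -1.03, and the adjusted p rose to between 0.0598 and 0.0908.

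The question of the main comparison was which genes differ in basal cells of Vim knockout mice. Of 8 tested Serpina3 genes in a cluster on chromosome 12, which encode secreted serine protease inhibitors, 5 rose. Serpina3g (log2 fold change 1.21, adjusted p = 0.266), Serpina3h (0.70, adjusted p = 0.927) and Serpina3i (-0.35, adjusted p = 0.929) were not called. Serpina3n (positions 104406708 to 104414329) rose from 31.0 ± 13.0 CPM (SD, n = 2) to 567 ± 56.9 CPM (SD, n = 4), a log2 fold change of 4.19 (SE 0.28, adjusted p = 0.00132). Serpina3m (104387164 to 104394257) had 0 and 1 counts in the wild-type libraries and 665, 596, 671 and 492 in the knockout libraries, a ratio of 1270 (95% counting interval 228 to 50202, adjusted p = 8.02e-05). Its log2 fold change by edgeR was 9.98, and 8.99 without wild type 1 and 12.3 without wild type 2. Serpina3f (104214544 to 104221129) rose from 0.252 ± 0.0303 to 15.6 ± 2.40 CPM (log2 fold change 5.92, SE 0.29, adjusted p = 1.51e-04). Serpina3k (104338486 to 104345739) and Serpina3c (104146907 to 104153872) had 0 counts in both wild-type libraries, and against a floor of 3 counts over the group they were at least 57.8-fold and 29.4-fold higher in the knockout (adjusted p = 0.0129 and 0.0319). Serpina3c lies below the expression limit of the naming rule and was named after its values were seen. Each of the 5 genes that rose was higher in 4 of 4 knockout libraries and in both experiments. Serpina3k was not called without wild type 1 (adjusted p = 0.0824), knockout 2 (0.0762) or knockout 3 (0.0572), and Serpina3c was not called when any 1 of the 6 libraries was left out (adjusted p from 0.0556 to 0.208). These genes are close paralogs, and Serpina3f lies within the annotated span of Serpina3g, so the share of each in the reads is uncertain.

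**Figure D2:**
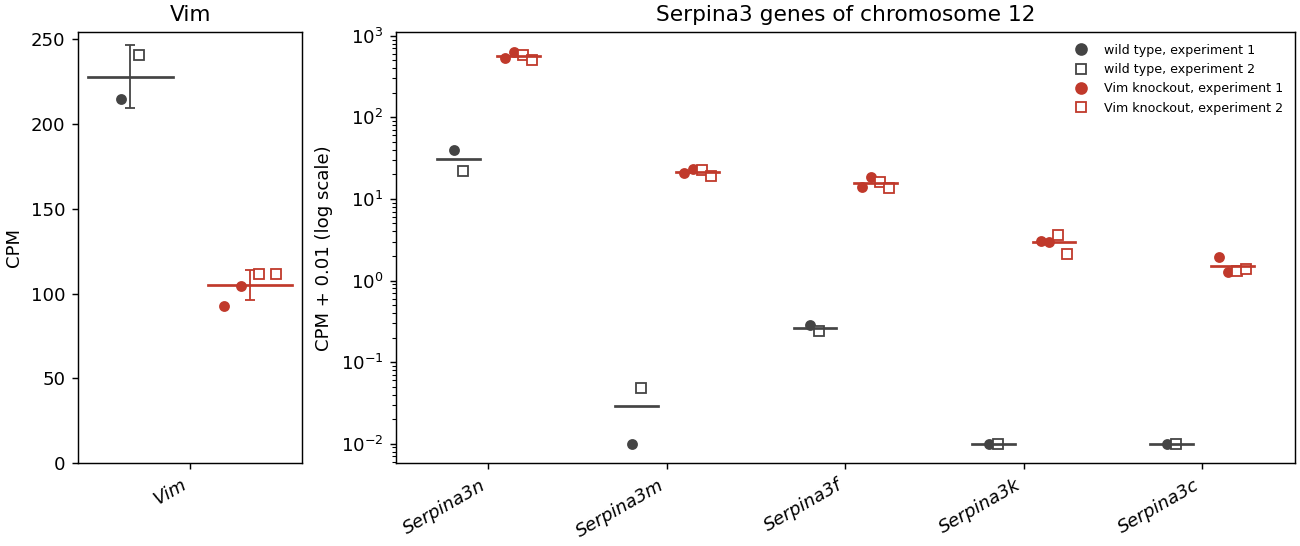
CPM of Vim on a linear axis (left) and CPM plus 0.01 of 5 Serpina3 genes on a log axis (right) per library, with wild type in grey, knockout in red, filled circles for experiment 1, open squares for experiment 2, horizontal lines for group means and error bars on the left for the SD. Knockout libraries hold 92.4 to 111 CPM of Vim, and all of them lie above both wild-type libraries for each Serpina3 gene.

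Altogether 11 genes were called, 8 higher and 3 lower. Besides the Serpina3 genes, Ankrd1, a muscle ankyrin-repeat protein and a known YAP target, rose from 2.80 ± 0.825 to 21.3 ± 3.91 CPM (log2 fold change 2.93, SE 0.27, adjusted p = 0.011). Wnt11, a secreted Wnt ligand, rose with a log2 fold change of 1.54 (SE 0.19, adjusted p = 0.0482) and Pamr1 with one of 1.51 (SE 0.17, adjusted p = 0.0237). Sele, which encodes the endothelial adhesion molecule E-selectin, fell by 1.64 on the log2 scale (SE 0.18, adjusted p = 0.0218), and the milk protein gene Csn1s2a fell by 5.41 (SE 0.59, adjusted p = 0.0218) from a low level of 5.40 ± 3.55 CPM. At an unadjusted p under 0.05 there were 1193 genes, against 696 expected by chance. DESeq2 called 163 genes higher and 99 lower. Ankrd1 was not called without wild type 1 (adjusted p = 0.0824) or knockout 3 (0.0572), and Pamr1 was not called when any 1 library was left out (0.054 to 0.208). Wnt11 was called only without knockout 2 (0.0324 there, otherwise 0.0631 to 0.285) and Sele only without knockout 1 (0.0365 there, otherwise 0.0501 to 0.208). Csn1s2a was called without knockout 1 (0.0365) and wild type 2 (0.0141) and not without the others (0.0907 to 0.208) or by limma-voom, and its log2 fold change was -4.49 without wild type 1 and -6.09 without knockout 1. Serpina3m, Serpina3f and Serpina3n were called whichever library was left out, while the count of calls ran from 3 without knockout 3 to 15 without knockout 1 and was 4 without wild type 1, 5 without knockout 2 and 5 without knockout 4.

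With the replicate block 217 genes were called, 156 higher and 61 lower, and all 11 were among them. In a single simulated data set 10.2% of the calls of this fit were false. The genes of the same naming rule in this fit included Frmpd4 (log2 fold change 2.62, SE 0.27, adjusted p = 0.00248), Ctse (2.86, SE 0.42, adjusted p = 0.0202), Dapk2 (2.57, SE 0.33, adjusted p = 0.00638) and Loxl4 (2.13, SE 0.27, adjusted p = 0.00638) among those that rose. Csn2, which encodes beta-casein, fell by 6.19 (SE 0.72, adjusted p = 0.0212), the endothelial nitric oxide synthase gene Nos3 by 2.06 (SE 0.40, adjusted p = 0.0397) and the growth factor gene Igf2 by 1.84 (SE 0.36, adjusted p = 0.0395). This count was 4 without wild type 1, 34 without wild type 2, 66 without knockout 4, 138 without knockout 3 and 940 without knockout 1.

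Among the 31 gene lists, 12 were called by camera, 8 higher and 4 lower, and 13 with the replicate block. With an estimated correlation 0 lists were called, and the smallest was adjusted p = 0.310 with an estimated correlation, or 0.228 with the block. By fry 0 lists were called and 6 had an unadjusted p under 0.05. The largest shift was in endothelial markers, whose 21 tested members all had negative log2 fold changes with a median of -1.79 (camera adjusted p = 1.03e-23, adjusted p = 0.322 with an estimated correlation). None passed over all genes and 16 were lower when adjusted over the list alone. Cdh5 was at 22.0 ± 15.1 CPM in wild type and 4.50 ± 1.56 in knockout, Aqp1 at 51.3 ± 32.6 and 14.9 ± 3.83, and Pecam1, which encodes the CD31 used to exclude endothelium, at 21.2 ± 12.9 and 5.43 ± 1.80 (SD, n = 2 and 4). Wild type 1 had the highest level of Pecam1, at 30.4 CPM against 12.1 in wild type 2. Without wild type 1 the median of the list was -0.75 and the list was still called (camera adjusted p = 2.10e-06), and without wild type 2 the median was -2.40.

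**Figure D3:**
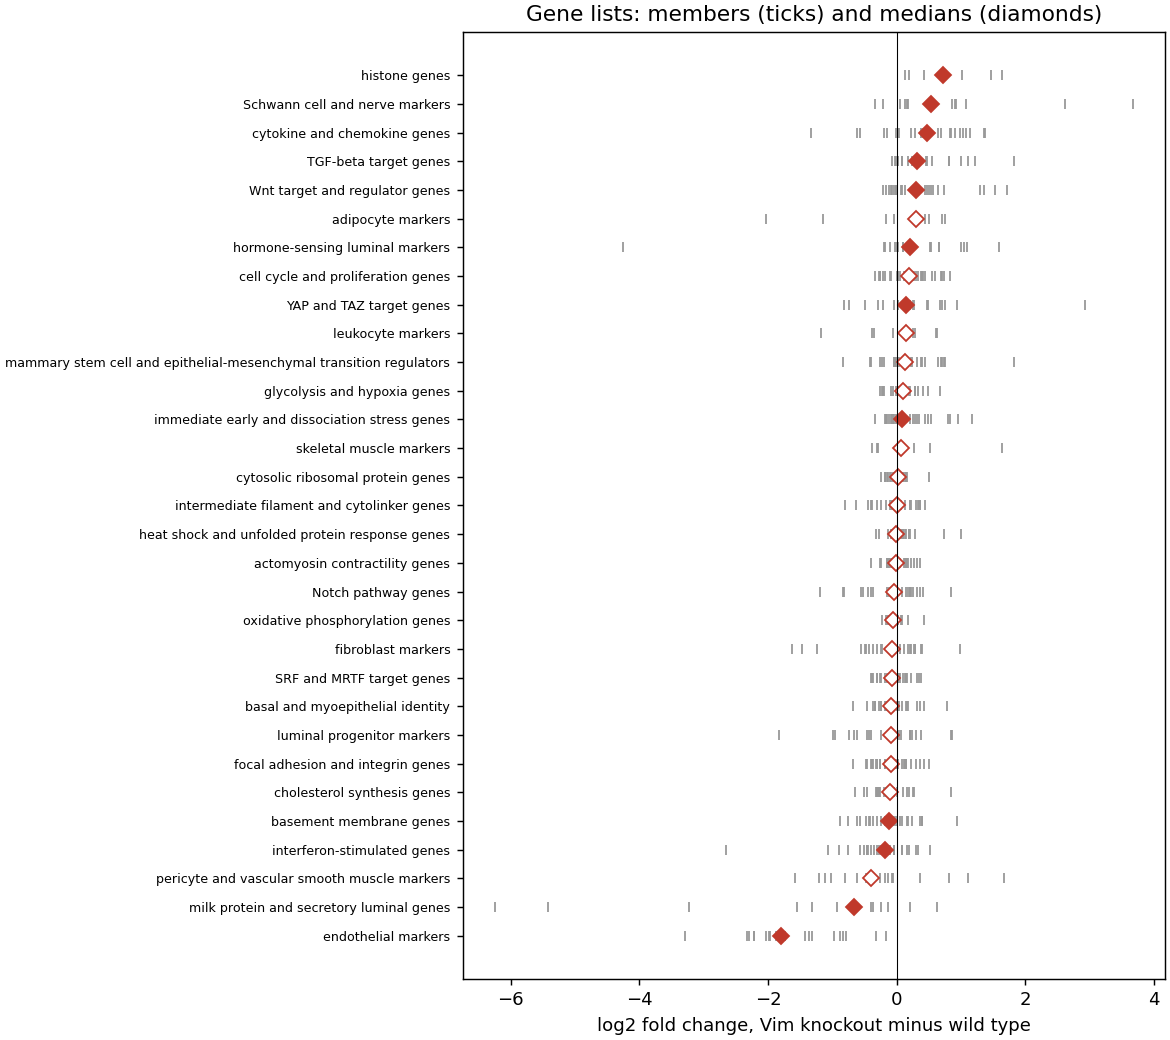
Log2 fold change of each tested member (ticks) and the median (diamonds) of the 31 lists, with filled diamonds for lists with a camera adjusted p under 0.05. Medians run from -1.79 for endothelial markers to 0.72 for histone genes.

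**Figure D4:**
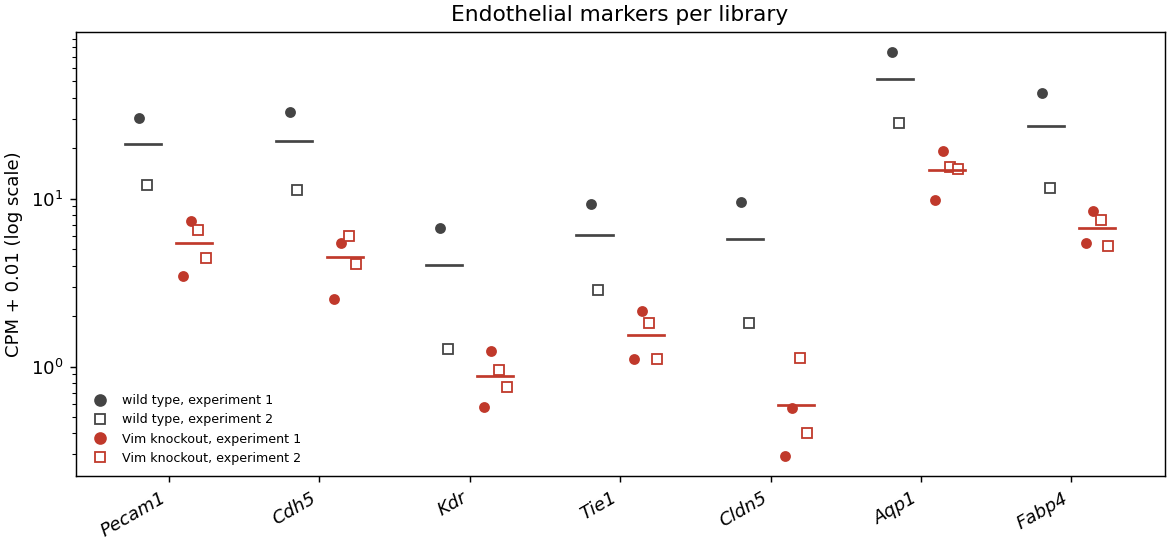
CPM plus 0.01 of 7 endothelial markers on a log axis per library, with wild type in grey, knockout in red, filled circles for experiment 1, open squares for experiment 2 and lines for group means. Pecam1 is at 30.4 and 12.1 CPM in wild type and between 3.46 and 7.35 CPM in the knockout.

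Milk protein and secretory genes were also lower as a list, with a median of -0.66 over 12 members (camera adjusted p = 8.71e-08, adjusted p = 0.322 with an estimated correlation). Csn1s2a was the 1 member that fell over all genes, 3 fell when adjusted over the list alone, and with the replicate block 2 fell. The median was -0.22 without wild type 1 and -1.10 without wild type 2. Basement membrane genes had a median of -0.12 over 25 members (camera adjusted p = 0.0126, adjusted p = 0.426 with an estimated correlation). None passed over all genes, 4 fell when adjusted over the list alone, and with the replicate block the collagen IV gene Col4a5 (log2 fold change -0.76, SE 0.11, adjusted p = 0.0102) and the nidogen gene Nid1 (-0.58, SE 0.12, adjusted p = 0.0463) fell. This list was not called without wild type 2 or without knockout 4 (adjusted p = 0.198 and 0.0541), and its median was -0.22 without wild type 1 and -0.07 without knockout 2. Interferon-stimulated genes had a median of -0.18 over 29 members, none of which passed over all genes or when adjusted over the list alone (camera adjusted p = 0.0102, adjusted p = 0.673 with an estimated correlation). That call was lost without knockout 2 (median -0.01, adjusted p = 0.279) and without wild type 2 (median -0.08, adjusted p = 0.187), and the median was -0.36 without knockout 4.

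TGF-beta target genes were higher as a list, with 19 of 22 members above 0 and a median of 0.32 (camera adjusted p = 2.37e-09, adjusted p = 0.310 with an estimated correlation). None passed over all genes and 7 were higher when adjusted over the list alone. With the replicate block 5 rose, among them fibronectin, Fn1 (log2 fold change 1.81, SE 0.18, adjusted p = 0.00282), and Id3 (1.25, SE 0.17, adjusted p = 0.0136). Wnt target and regulator genes had a median of 0.30 over 26 members (camera adjusted p = 1.16e-06, adjusted p = 0.322 with an estimated correlation), with Wnt11 the 1 that rose over all genes and 4 that rose when adjusted over the list alone. Without knockout 2 the median was 0.12 and the list was still called (adjusted p = 2.33e-05). With the block, Sfrp1, a secreted Wnt inhibitor (1.35, SE 0.14, adjusted p = 0.00248), and Apcdd1 (1.29, SE 0.24, adjusted p = 0.0322) rose too. YAP and TAZ target genes had a median of 0.15 over 23 members (camera adjusted p = 5.38e-04, adjusted p = 0.344 with an estimated correlation). Ankrd1 rose over all genes, 5 rose and 2 fell when adjusted over the list alone, and with the block Amotl2 rose (0.93, SE 0.10, adjusted p = 0.00303) while Nt5e fell by 0.74 (SE 0.13, adjusted p = 0.0249). Without wild type 1 this list was not called (median 0.03, adjusted p = 0.386), and the median was 0.31 without wild type 2, 0.23 without knockout 2 and 0.10 without knockout 4.

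Cytokine and chemokine genes had a median of 0.47 over 26 members (camera adjusted p = 2.69e-04, adjusted p = 0.564 with an estimated correlation). None passed over all genes or when adjusted over the list alone, and without wild type 1 the list was not called (adjusted p = 0.364), while without wild type 2 the median was 0.90. With the replicate block 10 were higher and 3 lower when adjusted over the list alone, and over all genes 6 rose, among them the NF-kB inhibitor gene Nfkbia (0.86, SE 0.13, adjusted p = 0.0139) and Lif (0.71, SE 0.11, adjusted p = 0.0154). Immediate early genes had a smaller median of 0.08 over 31 members (camera adjusted p = 0.0102, adjusted p = 0.673 with an estimated correlation), and without knockout 2 the median turned to -0.03 and the list was not called (adjusted p = 0.312). The median was 0.20 without wild type 1, 0.02 without wild type 2, 0.13 without knockout 1 and 0.13 without knockout 4. None of its members passed over all genes or when adjusted over the list alone, and Dusp5 (0.99, SE 0.12, adjusted p = 0.00461) rose with the block, where 4 were higher when adjusted over the list alone. Histone genes had a median of 0.72 over 6 members (camera adjusted p = 1.89e-04, adjusted p = 0.322 with an estimated correlation), with 2 higher when adjusted over the list alone, and without wild type 2 they were not called (adjusted p = 0.237). Only 6 of the 26 listed histone genes were tested. Their median was 1.66 without wild type 1 and between 0.42 and 0.45 without wild type 2, knockout 1 or knockout 4.

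The Schwann cell and nerve list was written for another cell type but shares Sox10 with the stem cell and epithelial-mesenchymal transition list. It had a median of 0.53 over 13 members (camera adjusted p = 1.89e-04, adjusted p = 0.500 with an estimated correlation). None passed over all genes and 2 were higher when adjusted over the list alone; Cdh19 had a log2 fold change of 2.62 (SE 0.50, adjusted p = 0.176). The list was not called without wild type 2 (adjusted p = 0.165), and its median was 0.80 without wild type 1. Hormone-sensing luminal markers had a median of 0.21 over 22 members (camera adjusted p = 0.00303, adjusted p = 0.564 with an estimated correlation), with 2 higher when adjusted over the list alone, and were not called without knockout 1 (median 0.03, adjusted p = 0.0875) or without wild type 2 (median 0.01, adjusted p = 0.760). Their median was 0.76 without wild type 1. Of the 22 members, 17 were above 0 and 5 below. Calca fell by 4.25 on the log2 scale (SE 1.40, edgeR adjusted p = 0.41), from 39.8 ± 51.7 to 2.04 ± 3.4 CPM (SD, n = 2 and 4). With the replicate block 5 members were higher and 1 lower when adjusted over the list alone. Stem cell and epithelial-mesenchymal transition regulators had a median of 0.14 over 26 members and an adjusted p = 0.0792, and the median was 0.29 without wild type 1, 0.21 without knockout 1 and 0.08 without knockout 2. The list was called with the replicate block (adjusted p = 0.0178, adjusted p = 0.316 with an estimated correlation), and Fn1 and Fermt1 rose, the latter named after its values were seen.

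Basal identity genes did not pass the test, with a median of -0.08 over 26 members (camera adjusted p = 0.359), and 0 members passed over all genes or when adjusted over the list alone by edgeR. With the replicate block 0 passed over all genes, and 3 were higher and 1 lower when adjusted over the list alone. Krt14 was at 4234 ± 465 CPM in wild type and 4236 ± 233 in knockout, Krt5 at 2318 ± 57.7 and 1957 ± 275, Trp63 at 719 ± 31.0 and 681 ± 61.0, Acta2 at 4001 ± 178 and 3391 ± 602, and Itga6, which encodes the CD49f of the gate, at 1188 ± 184 and 1046 ± 48.2 (SD, n = 2 and 4). Snai2, a transcription factor of mammary stem cells, had a log2 fold change of -0.23 (SE 0.19, adjusted p = 0.868). Cd24a had one of 0.52 (SE 0.16, adjusted p = 0.356, or 0.0585 with the replicate block). The luminal keratin genes Krt8 and Krt18 had log2 fold changes of -0.11 (SE 0.13, adjusted p = 0.932) and 0.22 (SE 0.12, adjusted p = 0.736). Ptprc, which encodes CD45, had 15 and 0 counts in wild type and 4, 1, 0 and 2 in knockout and was not tested.

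The lists of focal adhesion (camera adjusted p = 0.202), actomyosin (0.997), intermediate filament (0.912), SRF target (0.359), Notch (0.932), cell cycle (0.205), heat shock (0.214), cholesterol (0.246), glycolysis and hypoxia (0.199), oxidative phosphorylation (0.359) and ribosomal protein genes (0.855) were not called. The same held for luminal progenitor (0.359), fibroblast (0.167), pericyte (0.131), leukocyte (0.997), adipocyte (0.894) and skeletal muscle markers (0.671). Without wild type 1, the focal adhesion list was called lower (adjusted p = 0.00841), cell cycle genes higher (7.76e-06), cholesterol genes lower (0.0403) and luminal progenitor markers higher (0.0403). Without wild type 2, luminal progenitor (1.92e-05), pericyte (0.00367) and leukocyte markers (0.0133) were called lower. Pericyte markers were also called lower without knockout 2 (0.0459) and knockout 3 (0.0448), cell cycle genes higher without knockout 2 (0.0192), glycolysis genes higher without knockout 1 (0.0159) and fibroblast markers lower without knockout 3 (0.00644). The median and the test differed in sign for the intermediate filament, Notch, heat shock and adipocyte lists, the mean and the test for the actomyosin, Notch and leukocyte lists, and the median and the mean for the intermediate filament, actomyosin, heat shock, leukocyte and adipocyte lists. Among intermediate filament genes, Nes, which encodes nestin, was at 294 ± 21.8 CPM in wild type and 168 ± 45.5 in knockout (log2 fold change -0.81, SE 0.22, adjusted p = 0.283).

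The mice were of a mixed 129/Sv and C57BL/6 background, which raises the question whether genes linked to Vim differ. Of 74 tested genes within 10 Mb of Vim, the targeted gene was the 1 called, so Fisher's exact test there (2-sided, p = 0.0570) rests on Vim alone. Without Vim, in a count added after the data were seen, 0 of 73 neighbours were called by edgeR, DESeq2 or limma-voom, and 6, 5 and 6 had an unadjusted p under 0.05, against 6.25, 6.51 and 6.22 expected at the share of all other tested genes. The neighbour Fam107b was called with the replicate block (log2 fold change 0.55, SE 0.11, adjusted p = 0.0462), where 11 neighbours had an unadjusted p under 0.05, against 9.95 expected at the share of all other tested genes.

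The 2 experiments differed at 895 genes, 472 higher and 423 lower in experiment 2, in a model with genotype. The chemokine gene Cxcl2 was higher in experiment 2 by a log2 difference of 1.36 (adjusted p = 6.88e-04), Scnn1g, a sodium channel subunit gene, was higher by 1.83 (adjusted p = 5.95e-04), and the oxytocin receptor gene Oxtr was lower there with a log2 difference of -1.43 (adjusted p = 3.05e-04); these were chosen after their values were seen. The count was 38 without wild type 1, 42 without wild type 2, 120 without knockout 4, 482 without knockout 3 and 1838 without knockout 1. Within the experiments, knockout minus wild-type log2 differences correlated across genes (Pearson r = 0.399, Spearman rho = 0.297, genes not being independent replicates), and 59.5% of genes had the same sign. The genotype effect differed between the experiments at 0 genes by edgeR, with 586 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.523. That test has 2 residual degrees of freedom, all from knockout libraries, and assumes that the lone wild-type library of each experiment varies alike.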

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

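All tests of explanations here were chosen after the results were seen, except the count of other splits, and the criteria for the acute-phase, endothelial and dissociation tests were made stricter after a first look. A single knockout library stood apart from the other 3, by the gap to its neighbour over the range, in 6 of 146 groups examined, near the 1 in 20 that chance gives. These were Ilk (0.835, knockout 1 at 200 CPM), Ltbp2 (0.879, knockout 2 at 2145 CPM), Rps23 (0.841, knockout 4 at 3.70 CPM), Calca (0.896, knockout 1 at 7.11 CPM), Serpina3c (0.835, knockout 1 at 1.95 CPM) and the mean of ribosomal protein genes (0.838, knockout 3 at 6.22 log2 CPM). Of the 31 lists, 3 moved one way in both knockout libraries of experiment 1 and the other way in both of experiment 2. These differences were not tested. With a lone wild-type library per experiment such a pattern can readily arise by chance. The number that chance would give was not computed, so the 3 are given as values only. Experiment 2 minus experiment 1 was -0.0925 for intermediate filament genes, -0.191 for actomyosin genes and 0.784 for luminal progenitor markers.

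Misassigned Serpina3n reads at a share equal in both genotypes are argued against as the whole source of the rise of the other Serpina3 genes. A share that differs between the genotypes was not tested. At the knockout share of 7.35% of the Serpina3n count, Serpina3m, Serpina3f, Serpina3k and Serpina3c together would hold 138 wild-type counts (95% interval 116 to 162), and 16 were counted; this leaves the rise of Serpina3n itself. A strain haplotype carried with the knockout allele or in the colony cannot be told apart from the genotype. The design does not vary them separately. In the fit with the replicate block, 0 of the tested neighbours within 2 Mb were called. As that fit called 217 of 13925 genes, few calls would fall among so few neighbours, and the 0 decides nothing. An acute-phase and STAT3 response stays open. By genotype alone, the other 25 members of that list, written after the rise was seen, had a median of -0.05 (95% bootstrap interval -0.11 to 0.25). That bootstrap drew genes, not libraries. Of the 25 members, 12 were above 0, and 0 were called with or without the replicate block. With the block, camera with an estimated correlation gave p = 0.654.

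Endothelial cells carried through the CD31-negative gate, more of them in wild type, cannot be told apart from lower expression of these genes in the sorted cells, since the markers that showed the pattern were the ones counted. Of the 21 markers, 100% were lower within experiment 1 and 85.7% within experiment 2, with medians of -2.43 and -0.75, Aqp1 among the abundant ones and 12 markers still at 1 CPM or more in knockout. Eng, the most abundant in knockout, had log2 differences of -0.49 and 0.28, and Fabp4 is the 1 marker also on another list. Sele and Nos3, endothelial genes outside this list, also fell, and carry-over cannot be told apart for them either. A lower share of basal cells in wild type that raised every other cell type alike is argued against only for the list medians over all 6 libraries. The lowest bootstrap bound of the fibroblast, leukocyte, pericyte and adipocyte medians was -1.14, above the endothelial median of -1.79. The bootstrap drew genes, not libraries, and single fibroblast markers fell nearly as far, such as Lum (-1.46) and Dpt (-1.62). Of 25 fibroblast markers, 14 were below 0 and 11 above. Without wild type 1 the endothelial median was -0.75, above the bound of -1.14, with the other medians between 0.03 and 0.47. Without wild type 2 it was -2.40, against -0.75 for pericyte, -0.53 for leukocyte, -0.15 for fibroblast and 0.18 for adipocyte markers. The bootstrap was not repeated with a library left out, and a lower purity of wild type 1 alone was not tested. A difference of genotype in endothelial cells or in expression by basal cells was not tested, and both stay open with carry-over.

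A stronger response to tissue dissociation in the knockout is a candidate explanation for the higher cytokine and chemokine genes. Their medians were 0.41 and 0.55 within the experiments, against 0.0924 and 0.104 for immediate early genes. The bootstrap interval of the latter reached below 0 in experiment 2 (-0.0259 to 0.313). It drew genes, not libraries, and so holds no variation between libraries. The test therefore does not decide, and no biological explanation was tested.

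For the 895 genes that differed between the experiments, 10 splits of 6 libraries cannot give a share under 0.05. The real split was the 1 with as many genes, and the highest of the others gave 0.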

How the results depend on the processing

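The alternatives to the fit with the replicate block, 217 genes against 11 without it, were chosen after seeing the data. Vim stayed lower under every alternative, with log2 fold changes from -1.18 to -1.03 when 1 library was left out and -1.21 with the number in the titles as a block on 4 libraries, where the adjusted p was 0.0619. Of 11 called genes, 11 were shared with DESeq2, which called 262, and 10 with limma-voom. Leaving out 1 library gave 3 to 15 genes. The cause of these differences was not tested. The fit with the block gave 541 genes without a low-count filter, 676 by DESeq2 and 4 to 940 with 1 library left out. The genes that differed between the experiments numbered 38 to 1838 with 1 library left out. Against 12 lists called by camera, 0 were called with an estimated correlation and 0 by fry. With the block 0 were called with an estimated correlation and 2 by fry, the cytokine list and the heat shock list, which camera did not call. Within 10 Mb of Vim, where Vim itself was the called gene, 0 or 1 genes were called with 1 library left out, 0 with the number block, 1 within 5 Mb and 1 by DESeq2 (Fisher's exact p = 1, the share near Vim then being lower than elsewhere because many more genes were called elsewhere).

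Lists whose direction reversed were all outside the 12 called, and the cause was not tested. With DESeq2 size factors these were actomyosin (adjusted p = 0.961) and leukocyte lists (0.982), and with the stricter filter actomyosin (0.961). Without a low-count filter they were intermediate filament (0.864), actomyosin (0.911), adipocyte (0.362) and leukocyte lists, the last called lower (0.0214, tested by camera). With the replicate block they were leukocyte (0.983) and adipocyte lists (0.984), and by fry the leukocyte list (0.995). With the number block they were basal identity and leukocyte lists (both 0.989), SRF targets and skeletal muscle (both 0.974), intermediate filament (0.858), adipocyte (0.841) and actomyosin lists (0.750). With 1 library left out the adjusted p ran from 0.0768 to 0.760 for basal identity, 0.541 to 0.989 for intermediate filament, 0.00841 to 0.726 for focal adhesion, 0.302 to 0.965 for actomyosin, 0.541 to 0.918 for Notch and 7.76e-06 to 0.458 for cell cycle genes. It ran from 0.0403 to 0.820 for cholesterol, 0.172 to 0.989 for ribosomal protein, 1.92e-05 to 0.575 for luminal progenitor, 0.00367 to 0.956 for pericyte, 0.0133 to 0.989 for leukocyte, 0.722 to 0.989 for adipocyte and 0.324 to 0.9503 for skeletal muscle lists. Of single genes, the log2 fold change of Krt14 ran from -0.0888 to 0.119 and that of Krt8 from -0.190 to 7.09e-04. Among other named genes and lists, the replicate block added 35 calls and took away 0, and DESeq2 added 45.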

Other observations

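The search over Reactome pathways was added after the data were seen. Of 650 pathways of 15 to 200 tested genes, in the fit with the replicate block (217 genes called), camera called 3, 1 higher and 2 lower. With an estimated correlation 0 were called, at a smallest adjusted p of 1. The Wnt ligand biogenesis pathway was higher (median log2 fold change 0.39 over 16 genes, adjusted p = 5.19e-05), and 3 of its genes rose. Besides Wnt11, Wnt9a (2.82-fold, adjusted p = 0.0136) and Wnt7b (2.13-fold, adjusted p = 0.0136) rose in that fit; they were chosen after their values were seen. The laminin interaction pathway was lower (median -0.16 over 30 genes, adjusted p = 0.0075), with 3 genes that fell, and the collagen degradation pathway was lower (median -0.13 over 49 genes, adjusted p = 0.0075), with 4 that fell and 1 that rose.

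In the same fit, among genes chosen after their values were seen, Tnfaip3 rose by a log2 fold change of 0.88 (SE 0.13, adjusted p = 0.0119) and is 1 of the 6 members of the cytokine and chemokine list that rose with the block. Nfkbie and Relb are on none of the 31 lists, and they rose by 0.88 (SE 0.14, adjusted p = 0.0161) and 0.52 (SE 0.10, adjusted p = 0.0335). Tnfaip3, Nfkbie and Relb were also higher in experiment 2 than in experiment 1 (log2 difference 0.68, 0.92 and 0.58, adjusted p = 0.0116, 0.00567 and 0.00844).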
